A study of Mus musculus with 4 samples.

How the data were processed

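Bcl11b chromatin immunoprecipitation was sequenced in 2 samples and input DNA in 2 samples, all from DN3 cells grown from mouse bone marrow; per the labels, cells were crosslinked with DSG and formaldehyde and immunoprecipitated with several antibodies mixed. The replicate numbers come from the labels, which do not say whether replicates came from separate cultures. The submitters' processing notes name the mm9 build, Bowtie 1.1.1, HOMER, SAMtools and bedtools. How the libraries were pooled, and the settings of the peak caller and of the reproducibility filter, are not given in the sources used here.

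The deposited list gives, per the file headers, counts of ChIP tags per peak. Its normalised tag count and its scaled input tags are signal values that the authors scaled to a library size, per the file headers. The focus ratio is a fraction from the peak caller, per the file headers. The score is the peak caller's ranking value, per the file headers. The fold over input, the fold over local surroundings and the clonal fold are ratios made by the authors' peak caller, per the file headers. The p-value per peak over input and over surroundings is also deposited by the authors; 2318 of those over input are listed as 0. Every peak spans 222 bp from start to end. ChIP tags divided by the normalised tag count gave a median of 6.79; the library size behind that factor is not given in the sources used here. The totals of the single libraries are unknown, so depth was described per peak.

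From these values, ChIP tags over fold gave scaled input tags, which were multiples of 0.932. Dividing by that step gave whole input tags within 0.05 for 100% of peaks with any input tag. The remaining 106 peaks lay at 0.50 of a tag and were taken as 0 input tags. Intervals are 95% exact (Clopper-Pearson) binomial intervals; they cover counting error only, since the reads carry no molecular identifiers. For a count of 0, a floor of 3 counts was used.

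Before the data were examined, the tests and the rule for named sites were fixed. Peaks per chromosome were tested with exact binomial tests against the share of 21631 protein-coding genes on 20 chromosomes, with Benjamini-Hochberg adjustment at 0.05. The fixed plan named the share of placed length, or of annotated genes where lengths were lacking. The limit to protein-coding genes was not part of that plan. Gene counts per chromosome came from a RefSeq table of the GRCm38.p6 assembly, whose coordinates were not used because the list is on mm9. Clustering was the share of peaks with another start within 10 kb, against 100 random placements. The rule named the 10 highest-scoring peaks; its other parts need genes. The comparison of X with autosomes, the ranking by fold, the limit of 20 input tags and the windows of 100 kb were chosen after the data were seen. A permutation test on peaks used 100000 resamples, but its p is not reported here, and peaks are not replicates.

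On simulated lists of 19703 peaks, the chromosome test found 100% of changed chromosomes and called something in 4% of unchanged lists. The planted changes were larger than most of those called in the data, and the simulated peaks were independent. These rates therefore do not carry over to smaller changes or to clustered peaks. On simulated lists of 2737 peaks, the clustering test called 100% of lists with planted neighbours and 0% of uniform ones. With 115 simulated peaks, the permutation test of medians called a difference in 7% of draws with none. That test gave none of the p-values in the results. Alternatives were stricter lists by score or fold, merging of nearby peaks, other distances and other expectations per chromosome.

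A genome and annotation of the mm9 build were not used here. Distances to genes, promoter shares, peaks per gene, the 15 gene lists and motifs were therefore not analysed here. Agreement of the replicates was not analysed here, since the list holds no value per library. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.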

Results

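The series maps where Bcl11b, a zinc-finger transcription factor required for commitment to the T-cell lineage, sat on chromatin in DN3 cells, a stage of pro-T cells that has not yet made a T-cell receptor. The cells were grown from mouse bone marrow progenitors on OP9-DL1 stroma, a feeder line that displays a Notch ligand and so drives progenitors along the T-cell path. Chromatin immunoprecipitation with a mixture of antibodies against Bcl11b was sequenced in 2 samples, and the input DNA was sequenced in 2 samples. The deposited list joins them into 1 set of peaks with 1 value per peak, so no spread between replicates can be given for any value here. Scores, folds and tag counts per peak are the authors' own, and positions are on the mm9 build as the list gives them.

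The list held 19744 Bcl11b peaks from these DN3 cells. Of these, 19288 lay on autosomes, 415 on X and 41 on sequences whose names end in random. The median peak held 138 ChIP tags (range 39 to 2086) and was enriched 25.7-fold over input, with quartiles of 19.3 and 38.5. The lowest fold in the list was 15.02, with 1393 peaks between 15 and 16 and 0 between 14 and 15. The median fold over the local surroundings was 10.8, and its lowest value was 4.

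The depth behind the folds was uneven. Most peaks rested on many ChIP tags and few input tags, with a median of 5 input tags and 106 peaks with 0. At the median of both, the fold was 29.6 with a 95% exact binomial interval from 12.4 to 92.6, which covers counting error only. Peaks with high folds were often peaks with little input: 60.3% of the 1000 highest folds had at most 2 input tags, against 9.87% of all peaks. The 1000 highest folds and the 1000 highest scores shared 246 peaks. Across peaks, which are not independent replicates, Spearman's rho was 0.465 between score and fold and 0.585 between ChIP and input tags, in a list whose lowest fold by itself keeps peaks of few ChIP tags to few input tags.

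The strongest Bcl11b site by score lay on chromosome 18 at 24831365 to 24831587, with 1920 ChIP tags, 7 input tags and a fold of 294 (95% exact interval 143 to 733). Against its local surroundings it stood out less: its local fold was 6.97, under the list's lower quartile of 7.53. Its focus ratio, 0.514, was under the list's 5th percentile of 0.608. The next sites by score were a pair on chromosome 11, at 101503099 to 101503321 and 101506984 to 101507206. They held 1934 and 1916 ChIP tags, with folds of 122 (interval 76.0 to 210) and 108 (interval 69.1 to 180). Their input, 17 and 19 tags, was also high for the list, whose 95th percentile was 11. The other 7 of the 10 highest scores lay on chromosomes 4, 6, 8 and 12. Pairs of peaks stood at 46588113 and 46596686 on chromosome 4, at 68192476 and 68201049 on chromosome 6, and at 94121995 and 94130556 on chromosome 12. The last site was at 19784534 on chromosome 8. Those 7 had 30 to 56 input tags each and folds from 25.5 to 41.7, close to or moderately above the median of the list. In the whole list, 78 peaks had over 20 input tags, a limit chosen after these values were seen.

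The highest fold, on chromosome 5 at 125586648 to 125586870, was listed as 538 from 251 ChIP tags and 0 input tags. Set against the 3 counts that a count of 0 allows, this site was at least 89.7-fold enriched by its listed ChIP tags; the exact interval, which also covers the counting error of the ChIP tags, began at 72.4. On chromosome 11, the site at 109286897 to 109287119 had 444 ChIP tags over 1 input tag, a listed fold of 476 with an interval from 85.0 to 18852. A site on chromosome 7 at 148133000 to 148133222 combined a high fold with more tags: 799 over 2 input tags, a fold of 428 (interval 118 to 3544).

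Whether Bcl11b sites followed the genes was asked by setting the peaks of each chromosome against its share of protein-coding genes. X carried the fewest peaks for its genes, 415 where its share gave 880, a ratio of 0.472 (95% exact interval 0.428 to 0.519; exact binomial test, two-sided, adjusted p = 1.95e-69). In the upper 50% by score, which follows ChIP tags, the X ratio was 0.118. Chromosome 7 had 1259 peaks at a ratio of 0.681 (interval 0.645 to 0.718; exact binomial adjusted p = 3.28e-51). Chromosome 12 had 896 peaks at 1.45 times its share (interval 1.36 to 1.54; exact binomial adjusted p = 1.12e-25). In all, 9 chromosomes had more peaks than their share, 4 had fewer, and 7 of the 20 did not pass. The test takes peaks as independent, although they were clustered. Merging peaks within 10 kb left 7 above and 3 below, ending the calls of chromosomes 2, 11 (from 1.08 to 0.993) and 16. The upper 50% by score gave 6 above and 3 below. It ended the calls of chromosomes 1, 2, 6, 13, 15 and 18, and added 17 above (1.18) and 19 below (0.843). With the span covered by peaks as the expectation, chromosome 7 was at 1.096, chromosome 12 at 0.990 and X at 0.337. Against all annotated genes, the expectation planned where lengths were lacking, chromosome 12 was at 1.03 and did not pass (exact binomial adjusted p = 0.417). That expectation gave 9 above and 5 below. It ended the calls of chromosomes 1, 2, 12, 13 and 18, and added 4, 9, 17 and 19 above and 3 and 14 below. Per megabase, chromosome 11 was the densest, with 13.3 peaks, and X the sparsest, with 2.60.

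**Figure D1:**
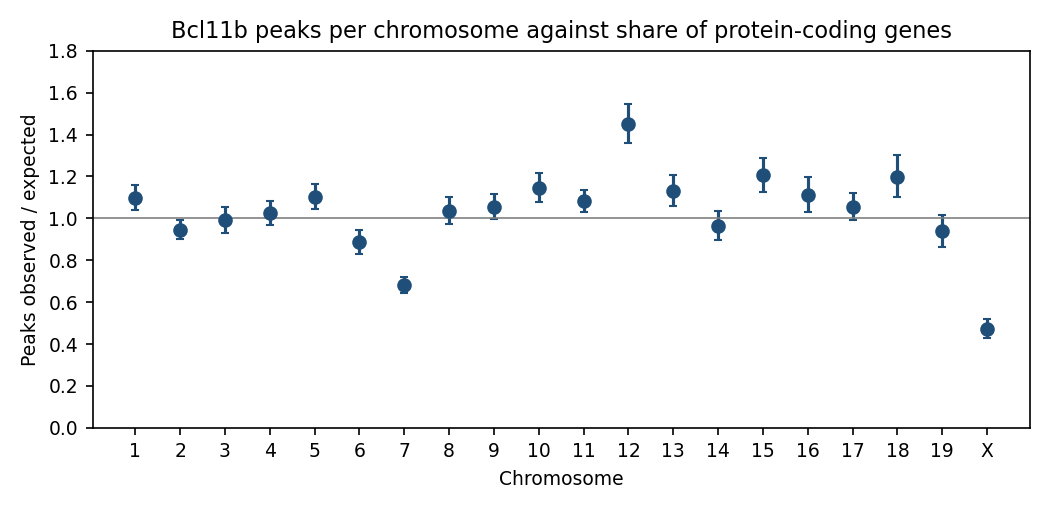
Peaks observed over expected from the share of protein-coding genes, for chromosomes 1 to 19 and X; points are ratios, bars are 95% exact intervals for counting error, and the line marks a ratio of 1. X lies at 0.472 and chromosome 12 at 1.45.

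Peaks on X also held fewer tags. The median X peak held 74 ChIP tags, whereas the medians of the 19 autosomes lay between 125 and 149 (mean 139 ± 6.56, SD over autosomes). This ratio of 0.533 was 0.873 in the upper 50% by score, which held 52 X peaks. The mean input was 3.16 tags on X and between 5.29 and 6.39 on autosomes. Enrichment was not lower among the listed peaks: the median fold over input was 28.6 on X and between 24.3 and 26.8 on the autosomes. The list holds no peak under 15.02-fold, and X peaks had a median of 3 input tags. It therefore cannot show whether X sites as a whole were less enriched. X was the most extreme of the 20 chromosomes in median ChIP tags, mean input tags and median fold. That gives the smallest two-sided p an exact permutation of the chromosomes allows, 0.05. Because X was singled out after the data were seen, this p adds no support. The measures are also linked, since the fold is ChIP tags over scaled input tags.

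**Figure D2:**
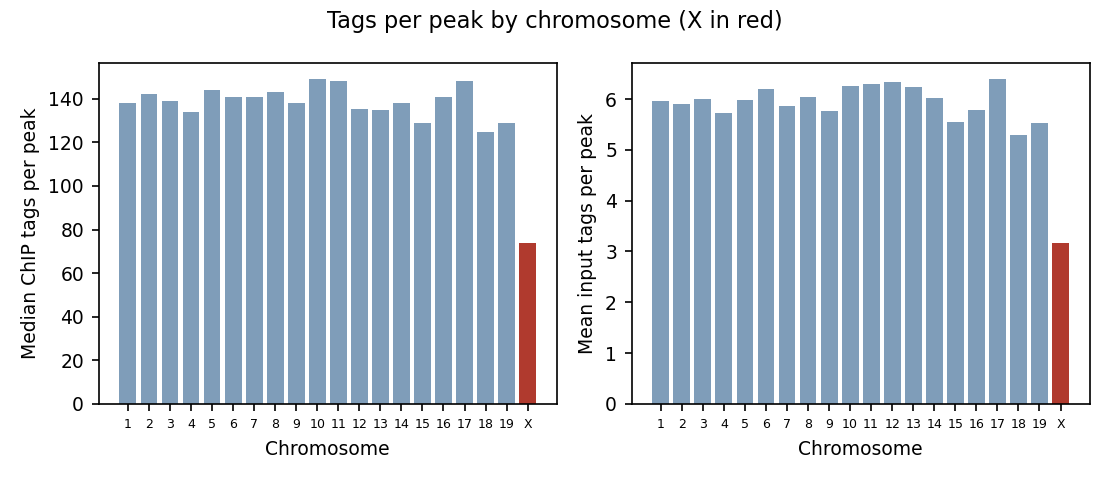
Median ChIP tags per peak (left axis panel) and mean input tags per peak (right axis panel) for chromosomes 1 to 19 and X, 1 bar per chromosome from the pooled list. X, in red, stands at 74 ChIP tags and 3.16 input tags, below every autosome in both.

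Bcl11b sites came in groups. Of the 19703 peaks on chromosomes 1 to 19 and X, 43.8% had another peak within 10 kb, against 15.2% ± 0.311 (SD over 100 random placements within the span each chromosome's peaks covered). The highest placement reached 16.0%, and the permutation p, two-sided, was 0.0099, the smallest that 100 placements can give. The placements ignored which parts of the genome reads can be mapped to. They also ignored where genes and open chromatin lie, so they show grouping only against positions drawn evenly along each chromosome. The densest windows of 100 kb, chosen after their values were seen, held 15 peaks each, on chromosome 13 from 51831994 to 51926400 and on chromosome 9 from 107449368 to 107547116. Their median ChIP tags were 227 and 136. A window on chromosome 16 from 10639294 to 10732855 held 14 peaks, with a median of 216 tags and a median fold of 37.2. No random placement put more than 10 peaks in a window.

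**Figure D3:**
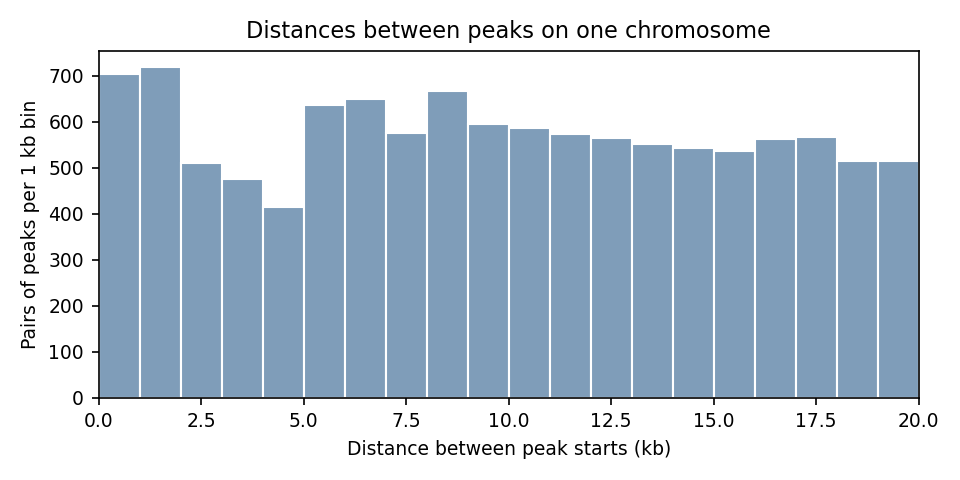
Number of pairs of peaks on one chromosome per 1 kb bin of the distance between their starts, up to 20 kb. The bin from 4 to 5 kb holds 414 pairs and the bin from 5 to 6 kb holds 635. The bins from 0 to 1 kb and 1 to 2 kb are the fullest, with 703 and 718.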

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

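The count below was singled out after the data were seen, because it lies outside the comparisons of chromosomes 1 to 19 and X. On 9 sequences whose names end in random, 41 peaks were listed, each at least 15.02-fold over input. They had a median of 157 ChIP tags and a median fold of 21.3. Of these, 16 (39.0%) had values identical in 6 columns to those of another peak, against 49 (0.249%) of the peaks on chromosomes 1 to 19 and X.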

How the results depend on the processing

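No paired analysis was possible because the list holds 1 value per peak and none per library; leaving out replicates was not run for the same reason. Other alternatives not run, for lack of an mm9 annotation or genome, were promoter distances, limits on distance to genes, gene backgrounds and motif windows. Alternatives using fold, identical values, the span, autosomes only and X tags were chosen after seeing the data. The share of all annotated genes was planned as the expectation where chromosome lengths were lacking. The main results used protein-coding genes instead, which the plan did not name. X held 2.10% of peaks, but 0.524% of the upper 50% by score, 0.320% of the upper 25% by score and 2.36% of the upper 50% by fold. The score follows tags, which were lower on X, so score thresholds remove X peaks. By construction, these lists held 9921, 5003 and 9876 peaks. The tag ratio of X to autosomes, 0.533, was 0.873 in the upper 50% by score, where 52 X peaks remained, and 0.483 in the upper 50% by fold. Counts of chromosomes above their share (6 to 9) and below it (3 to 6) stayed within 1.5 times of the main counts, but which chromosomes passed changed. Ratios crossed 1 as follows, and the cause was not tested. Against the span, chromosomes 1 (0.811), 2 (1.12), 7 (1.096) and 18 (0.837) passed the threshold on the other side, and 19, which had not passed at 0.937, passed at 1.35. Chromosomes 8 (0.9985), 12 (0.990), 13 (0.948) and 16 (0.944) crossed without passing. Against all annotated genes, 19 passed at 1.102, and 2 (1.04) and 13 (0.945) did not. Chromosome 19 passed below its share in the upper 50% by score (0.843) and on autosomes only (0.915). Merging within 10 kb put 3 at 1.04, 11 at 0.993 and 14 at 1.02; the upper 50% by score put 3 at 1.0006 and 4 at 0.989; autosomes only put 4 at 0.9996; none of these passed. Chromosome 12 was at 1.03 against all annotated genes, not past the threshold. X stayed below its share in all 5 alternatives that included it, from 0.118 to 0.529. Clustering stayed above random placements in all 5 alternatives, from 1.49 to 4.05 times. A median of 5 input tags per peak limits most folds.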

Other observations

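All tests in this part were chosen after the results were seen. The peak with the most input, on chromosome 11 at 3023979 to 3024201, held 107 input and 2086 ChIP tags, the most in the list of both, at a fold of 20.9. A pair on X at 166429184 and 166436030 held 48 and 53 input tags, whereas the next X peaks by score held 4 each.

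Some peaks had identical values in the 6 compared columns: in 32 groups, 65 peaks shared ChIP tags, score, input, focus ratio and the rest of those columns. An example is a trio on chromosome 14 at 26746791, 26886544 and 27026160. Among peaks of equal tag count, 100 shuffles gave a median of 6 and at most 15 groups. This argues against chance ties for the whole set, but some groups may be such ties. The shuffles moved score, focus ratio, input and clonal fold separately, which may lower the number of ties they give. The local fold, not used to find the groups, agreed within 10% in 72.7% of 33 pairs (95% exact interval 54.5 to 86.7), against 14.9% of tag-matched random pairs, so a candidate explanation is copied sequence with reads counted at each copy. The 3 pairs among the 10 highest scores on chromosomes 4, 6 and 12 drew attention by their spacings of 8573, 8573 and 8561 bp; drawing 33 peak distances, the number of pairs within 50 kb among the 100 highest scores, gave any 3 that close in 0.080% of 10000 draws, and 11 of 12 combinations of top scores and reach gave under 5% (range 0.030% to 7.14%). Mean input was 32.8 tags in these 6 peaks against 14.4 in 235 other autosomal peaks of 500 tags or more (ratio interval 1.96 to 2.63, counting error only). The input comparison decides nothing about unrelated single-copy sites. The 6 held 1102 to 1284 ChIP tags, input rose with ChIP tags, and their input had been seen beforehand. Of the 235, 29 had as much input as the lowest of the 6. The spacings do not exclude unrelated sites either. Copies of a provirus with a long terminal repeat at each end may be the source of the 3 pairs, as endogenous mammary tumour virus is known on these chromosomes in C57BL/6 mice, but no sequence was tested.

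Why peaks on X held fewer tags stays open between 1 copy of X for 2 of each autosome, as in male mice, and weaker binding at equal copy number. Among peaks of 200 to 300 ChIP tags, mean input on X was 3.80 tags (15 peaks) against 7.56 on autosomes (3353 peaks), a ratio of 0.503 (95% exact interval 0.381 to 0.652), and from 150 to 200 tags the ratio was 0.793 (interval 0.657 to 0.949), below 1 but above 0.50. Over all peaks of 200 tags or more it was 1.15 (interval 0.976 to 1.34), which rests on the X pair of 48 and 53 input tags: the medians there were 4 on X and 7 on autosomes. Most of the 415 X peaks had fewer ChIP tags, where the lowest fold of the list limits input and the ratio decides nothing. The sequence named Y_random carried 2 peaks, at 39642412 and 39650552, with 397 ChIP and 20 input tags each, but their reads may come from other copies. Copy number as the whole cause of fewer X peaks was not settled either. Halving autosomal tags left 75.02% of peaks above the lowest tags and fold of the list, against 47.2% of the gene share on X. The reproducibility filter was not simulated. Peaks are numbered by score within each chromosome, with gaps, up to 892 on X. At most 46.5% of X numbers were listed, against at most 29.7% to 42.0% on autosomes. Among the numbers seen, X thus lost no larger share than the autosomes. Numbers past the last listed peak are unseen, so losses there stay open.

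Pairs of peaks became more frequent from just under 5 kb to just over it. The bins from 0 to 1 kb and 1 to 2 kb were still the fullest, with 703 and 718 pairs. There were 1.53 times as many pairs 5 to 6 kb apart as 4 to 5 kb apart (95% exact interval 1.35 to 1.74), and no other neighbouring bins from 2 kb to 20 kb rose by more than 1.16 times. A local-background filter of the peak caller is a candidate explanation, so the shares of close neighbours may be too low. Peaks with a neighbour under 5 kb had a median local fold of 7, against 11.3 with a neighbour at 5 to 10 kb. Their ChIP tags were 1.04 times as high (149 against 143), which does not decide whether weaker peaks lie next to others, since the list keeps only peaks past a local fold of 4.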
